A study of Mus musculus with 6 samples.

How the data were processed

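Small RNA was sequenced from whole mouse ovary in 6 libraries, 3 from mice kept at normal pressure and 3 from mice kept under hypobaric hypoxia. Per the labels' protocols, total RNA was extracted with a column kit and 1.3 µg entered each library. Small RNA was selected on a polyacrylamide gel, ligated to adapters, reverse transcribed, amplified by PCR and read as single-end reads of 50 bases on a DNBSEQ instrument. The submitters' processing notes name Bowtie2, DESeq2 and the genome build GRCm38.p6, without their role or version. How predicted miRNAs were found and how reads that match several miRNAs were assigned are not given in the sources used here.

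The deposited table holds 1300 miRNAs, 1025 with a name from the annotation and 275 predicted ones. Its name calls the values TPM. The deposited values are reads per 1000000 reads (RPM) of a library total set by the authors: in each library every value is a whole multiple of what 1 read is worth. With a tolerance of 0.0005 RPM, 100% of the values in each of the 6 libraries came out as whole reads of exactly 1 implied total. What reads beyond the miRNAs that total holds is not given in the sources used here. The implied totals lie between 20800777 and 22559146 reads, so 1 read is worth 0.0443 to 0.0481 RPM, and 3 reads are worth 0.133 to 0.144 RPM. Reads without molecular identifiers are not independent molecules, so these floors cover counting error only. Within a group, no 2 libraries agree within sampling noise: the chi-square over degrees of freedom was at least 168.

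Groups and replicate numbers were taken from the library titles. The labels disagree in places. The altitude of the normal-pressure group is 1500 m in the titles and 1588 m in the design text. The simulated altitude is 6500 m in the titles, the treatment and the design text and 5000 m in the descriptions. The exposure is 15 days for all mice in the design text, while the descriptions give 15, 16 and 17 days by replicate number, and the dark phase of the normal-pressure mice is given as 12, 13 and 14 hours. Age is 8 weeks in the design text, and the descriptions give a range. The descriptions name levonorgestrel and ethinylestradiol for both groups but give doses (0.1 and 0.02 mg/kg) for the hypobaric group alone, so equal dosing is not stated. The labels name 15 mice per group and do not say whether a library holds 1 mouse or a pool. The p-values therefore measure the spread between these libraries, which may be partly technical. All libraries carry batch number 1.

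The main comparison was hypobaric hypoxia over normal pressure with limma 3.58.1 in R 4.3.3. The test was fixed for normalized values, so the recovered reads entered only alternatives. It was run on log2(RPM + 1), with an intensity trend of the variance, two-sided, and Benjamini-Hochberg adjustment over the 475 miRNAs with a mean of at least 1 RPM. Of these 448 are annotated and 27 predicted. The threshold was an adjusted p of 0.05. Fold changes are on the log2(RPM + 1) scale, which understates changes of low miRNAs. Levels are given as mean ± SD over 3 libraries and log2 changes with their standard error (SE). Of 23 miRNA lists fixed before the data were examined, the 21 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The lists cover hypoxia-associated, granulosa and luteal, p53-responsive, erythroid, endothelial, leukocyte, smooth and striated muscle, fibroblast, epithelial, ciliated, embryonic (miR-290 to miR-295 cluster), hepatocyte and neural miRNAs. They also cover the let-7, miR-29 and miR-30 families, the miR-17 to miR-92, miR-183 and Dlk1-Dio3 clusters, 2 X-linked clusters (miR-465 and miR-322), and the Sfmbt2 families. Counts for a list are given over all miRNAs tested and adjusted over the list alone.

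The miRNAs named were set by a rule, also fixed before the data were examined. It takes up to 10 per direction with the largest change among those past the threshold, filled to 10 by the smallest p. It adds the 8 most abundant, both arms of miR-210 with miR-202-5p, and the 2 members of each tested list with the smallest p. Any other miRNA named was chosen after its values were seen. Comparisons of a single value per library used an exact permutation test, two-sided, which cannot go below 0.1 with 3 against 3. They were run in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

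Precursors were matched by symbol to GENCODE vM21 on GRCm38, the assembly of the build in the submitters' notes, and 1006 of the 1025 annotated miRNAs (98.1%) had one. Coordinates are those of the precursor gene, counted from 1. Rows whose precursors share an identical stretch of at least 20 bases on the same arm were grouped. There are 31 such groups with 93 miRNAs, 65 of them tested, and their values are uncertain because reads can be assigned to either name.

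The fits were tested on simulated data for this comparison, 10 times, with counts drawn for the real miRNAs and 200 of them changed. About 474 passed the filter. limma recovered 93.6% of the tested miRNAs changed 4-fold and 31.3% of those changed 2-fold, and called 0.573% of unchanged ones. edgeR recovered 93.9% and 32.1%. The simulation drew each miRNA independently, with as many raised as lowered, while miRNAs of the real libraries deviate together. These rates need not hold for the real data.

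The alternatives fixed before the data were examined were a pseudocount of 0.1 or 10, no filter or a mean of at least 10 RPM, and median-of-ratios, quantile or reduced-total scaling. The others were limma without the trend or with robust variances, the replicate number as a block, leaving out each library, annotated miRNAs only, and count tests on the recovered reads. Those count tests were edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0. A summing of grouped rows, scaling to miRNA reads and leaving out a pair of libraries were chosen after seeing the data. So was a GC correction, which used the GC content of the precursor arms. No column of the table was left out.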

Results

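Mature miRNA levels were measured by small RNA sequencing in whole ovaries of female C57BL/6J mice after hormonal synchronization with levonorgestrel and ethinylestradiol, named in the labels of both groups with doses for the hypobaric group alone. One group of 3 libraries came from mice housed at the local altitude of 1588 m, at 83.56 kPa. The other 3 came from mice housed in a decompression chamber at 43.12 kPa, simulating 6500 m. The comparison asks which miRNAs differ in ovaries exposed to low-pressure hypoxia, a setting in which the submitters study ovarian injury. Each library held 20800777 to 22559146 implied reads, of which 6852198 to 8701696 were assigned to miRNAs. The miRNA share was 39.1% ± 1.73 (SD, n = 3) of reads under hypobaric hypoxia and 33.9% ± 3.14 (SD, n = 3) at normal pressure. The exact permutation test, two-sided, gave p = 0.1, the smallest possible with 3 against 3. Detected miRNAs numbered 973 ± 5.86 (SD, n = 3) under hypobaric hypoxia and 1037 ± 16.6 (SD, n = 3) at normal pressure, with exact permutation p = 0.1, two-sided.

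Under hypobaric hypoxia 15 miRNAs were higher and 8 were lower, 23 of the 475 tested, and in each of the 23 the groups did not overlap. Of these, 4 share a precursor stretch with another miRNA. Among them are miR-199a-3p and miR-199b-3p, called in opposite directions, whose sum did not pass (limma adjusted p = 0.281). The red-cell miRNA miR-451a rose 12.4-fold, and miR-210-3p, the best-known hypoxia-inducible miRNA, rose 2.80-fold. The clustered miR-212 and miR-132 fell, with log2 changes from -2.15 to -1.37, and so did miR-21a-5p and miR-96-5p. The gonad-enriched miR-202 rose in both arms. Fold changes are on the log2(RPM + 1) scale, which understates those of low miRNAs. Among all 475, the groups did not overlap in 127 (26.7%). For a single miRNA chance gives 10%. The miRNAs vary together across libraries, so by chance the share can lie far from 10%, and it was not computed for other splits. The median log2 change of all tested miRNAs was 0.15, and other scalings brought it to between -0.05 and 0.03; relative to it, miR-451a was at 3.48, miR-210-3p at 1.33 and miR-212-3p at -2.31. The share of higher calls was 65.2%, against 38.7% to 46.2% with those scalings. Median-of-ratios and quantile scaling each gave 12 higher and 14 lower, totals without the 10 most abundant miRNAs 12 and 19, edgeR 11 and 14, and DESeq2 32 and 31. Calls numbered 11 without hypobaric library 1 (5 higher, 6 lower), 10 without hypobaric library 2 (6 and 4), and 34 without hypobaric library 3 (25 and 9).

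**Figure D1:**
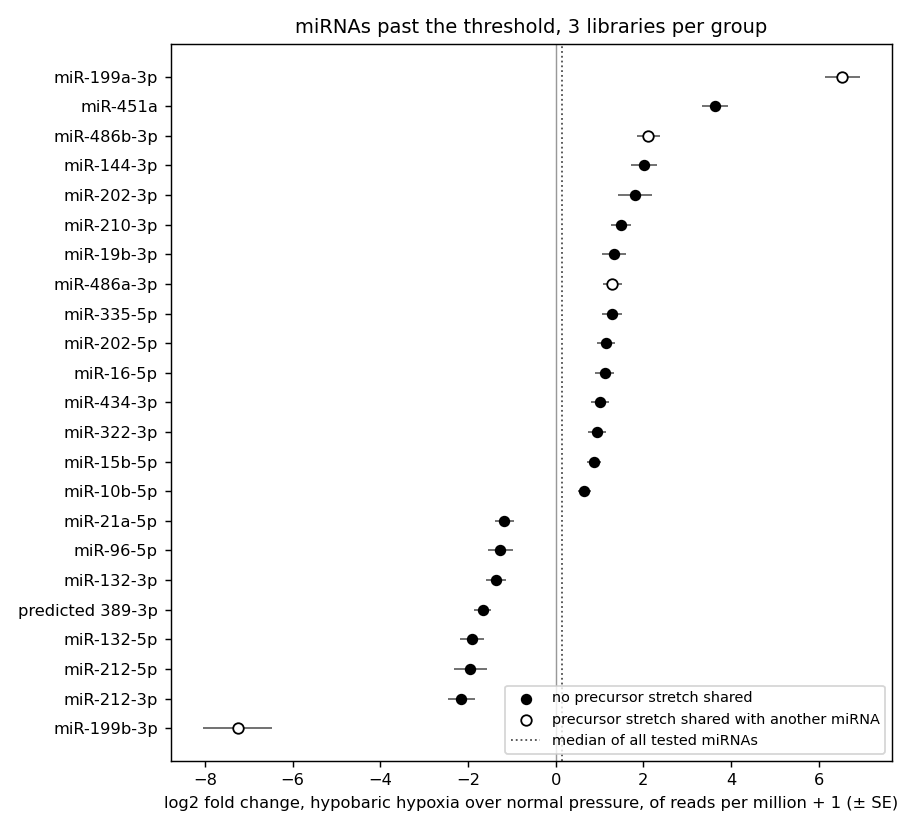
Log2 fold change (hypobaric hypoxia over normal pressure, log2 of RPM + 1, ± SE, 3 libraries per group) of the 23 miRNAs past the adjusted p threshold of 0.05 in limma. The 15 higher miRNAs reach 6.54 and the 8 lower reach -7.25, both in open symbols, which mark miRNAs whose precursors share a stretch with another miRNA; the dotted line is the median of all 475 tested, 0.15.

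The 10 most abundant miRNAs of a library held 51.1% to 53.8% of its miRNA reads. miR-143-3p, typical of smooth muscle and other mesenchymal cells, was at 28942 ± 4523 RPM at normal pressure and 28422 ± 2632 RPM under hypobaric hypoxia (SD, n = 3), the highest mean over the 6 libraries among the names as deposited. Next by that mean were miR-26a-5p, let-7c-5p, miR-99a-5p, the endothelial miR-126a-3p, let-7a-5p, miR-181a-5p and let-7b-5p. Reads of let-7a-5p and let-7c-5p can be assigned to either name, and their sum, 39576 ± 4258 and 44236 ± 1465 RPM (SD, n = 3), lay above miR-143-3p. None of these 8 passed in limma, and their log2 changes lay between -0.02 and 0.41. On the log2 scale the first principal component held 51.4% of the variance and separated the groups. The second held 28.1% and set normal-pressure library 2 and hypobaric library 3 (-6.78 and -9.11) apart from the other 4 (1.77 to 5.83). Without this pair 36 miRNAs were higher and 13 lower.

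The hypoxia-associated list, miRNAs described as raised in hypoxic cells, held 21 tested members, of which 1 rose, 1 fell and 19 did not pass, with the same counts adjusted over the list alone. The list did not pass (camera adjusted p = 0.170, median log2 change 0.29). Positive log2 changes were found in 17 of the 21, against 65.7% of all tested miRNAs. An unadjusted limma p under 0.05 was found in 9, against 96 of all 475 tested. Of those 9, miR-21a-5p and miR-24-3p had negative changes. Count tests called 3 members with edgeR and 5 with DESeq2. miR-210-3p rose from 4.17 ± 0.602 to 13.7 ± 3.25 RPM (SD, n = 3), a log2 change of 1.49 ± 0.23 (SE) with limma adjusted p = 0.00679. Its precursor lies on chromosome 7, 141221384 to 141221493, minus strand, outside any other annotated gene. The opposite arm, miR-210-5p, was at 0.976 ± 0.615 and 1.94 ± 0.479 RPM (SD, n = 3), with adjusted p = 0.234. The member that fell was miR-21a-5p, from 1729 ± 405 to 757 ± 123 RPM (SD, n = 3), a log2 change of -1.17 ± 0.22 (SE), adjusted p = 0.0148. Its precursor lies in an exon of Vmp1 on chromosome 11, 86584067 to 86584158. The call of miR-21a-5p was lost without normal-pressure library 1 (adjusted p = 0.0538) or hypobaric library 2 (0.0696).

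Of the erythroid list, miRNAs of red blood cells and their precursors, 4 of 6 tested members rose and none fell; adjusted over the list alone 5 rose. The median log2 change was 2.06, or 1.91 above that of all tested miRNAs, and the list passed with the preset correlation (camera adjusted p = 3.56e-05). It had an adjusted p = 0.202 with an estimated correlation, and fry gave an adjusted p = 0.00556 for a rise. All 6 tested members come from the locus of miR-451a and miR-144 or from that of miR-486. The preset correlation counts them as nearly independent, which they are not. miR-451a rose from 1005 ± 475 to 11858 ± 2831 RPM (SD, n = 3), a log2 change of 3.63 ± 0.31 (SE), limma adjusted p = 0.000215. Its precursor (chromosome 11, 78073170 to 78073241, plus strand, intergenic) lies beside that of miR-144 (78073005 to 78073070). miR-144-3p rose from 0.266 ± 0.141 to 4.40 ± 2.23 RPM (SD, n = 3), with adjusted p = 0.00570. miR-486a-3p and miR-486b-3p rose by 1.29 and 2.11 on the log2 scale. Their precursors lie on opposite strands of 1 locus on chromosome 8 (23142555 to 23142682), that of miR-486a in an intron of the erythrocyte ankyrin gene Ank1. Reads can be assigned to either name, and their sum rose by 1.73 ± 0.24 (SE) with adjusted p = 0.00063. The list did not pass with a filter at a mean of at least 10 RPM (camera adjusted p = 0.0630), and miR-486a-3p did not pass without hypobaric library 1 (adjusted p = 0.0536).

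**Figure D2:**
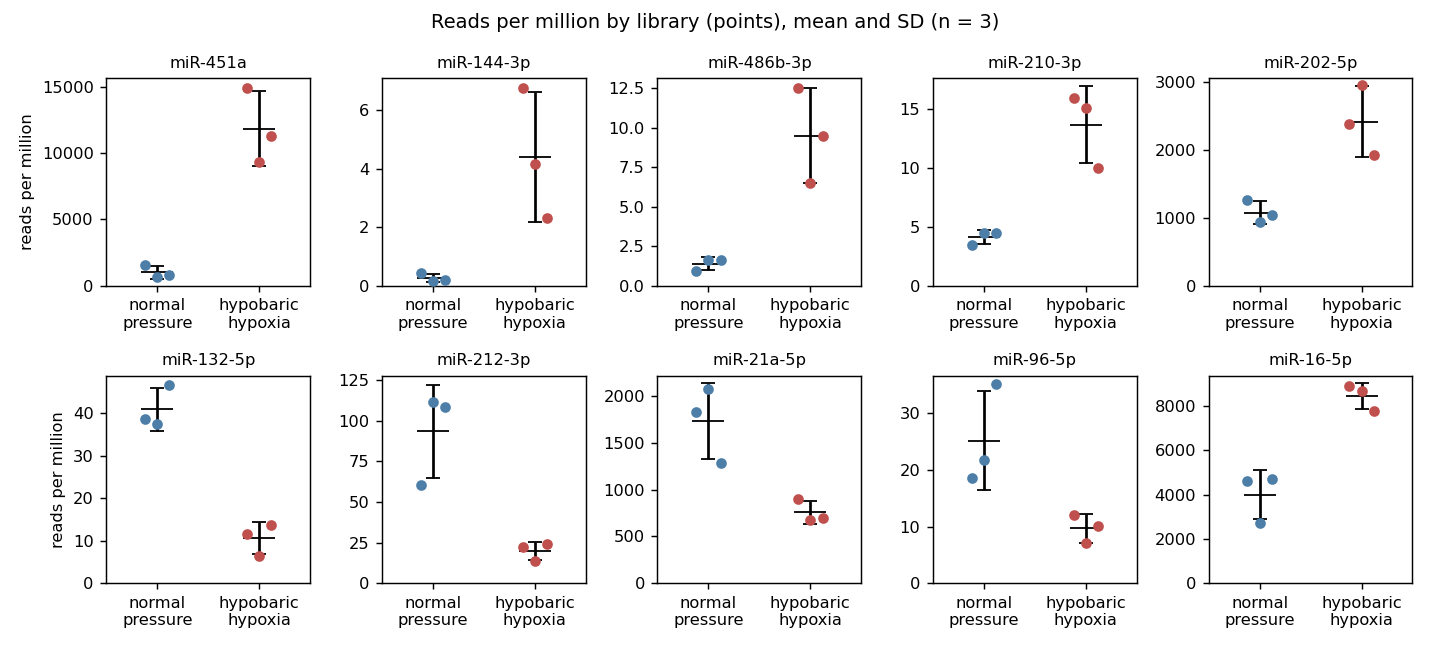
RPM of 10 miRNAs past the threshold in each library (points), with the mean and SD of 3 libraries per group. The vertical axes start at 0 and differ between panels; in every panel the 3 hypobaric points lie on 1 side of the 3 normal-pressure points.

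Of the granulosa and luteal list, miRNAs tied to gonadotropins or steroid production, 6 of 18 tested members fell, 2 rose and 10 did not pass; adjusted over the list alone 8 fell and 2 rose. The list passed as lower with the preset correlation (camera adjusted p = 0.000128), with a median log2 change of -0.31, or -0.47 relative to all tested miRNAs. It had an adjusted p = 0.557 with an estimated correlation. Both arms of the neighbouring miR-132 and miR-212 and the miR-183, miR-96 and miR-182 cluster enter the list as separate members. The preset correlation counts them as nearly independent, so the result rests largely on these loci. miR-212-3p fell from 93.5 ± 28.5 to 20.0 ± 5.57 RPM (SD, n = 3), a log2 change of -2.15 ± 0.31 (SE). miR-132-5p fell from 40.9 ± 5.01 to 10.6 ± 3.75 RPM (SD, n = 3), a log2 change of -1.90 ± 0.28 (SE), and both had limma adjusted p = 0.00513. The precursors lie side by side in an intron of the noncoding gene 1700016P03Rik on chromosome 11 (75173388 to 75173478 for miR-212 and 75173682 to 75173747 for miR-132). On the other arms, miR-212-5p fell by 1.95 and miR-132-3p fell by 1.37 on the log2 scale. The members that rose were miR-202-5p, from 1079 ± 164 to 2420 ± 518 RPM (SD, n = 3), and miR-202-3p, from 113 ± 62.0 to 377 ± 121 RPM (SD, n = 3), with limma adjusted p = 0.0114 and 0.0254. Their precursor lies in an exon of the lincRNA Gm2044 on chromosome 7 (139957689 to 139957760). Without hypobaric library 1 the adjusted p was 0.0797 for miR-212-5p, 0.0663 for miR-202-5p and 0.0987 for miR-202-3p, and without hypobaric library 2 it was 0.0743, 0.0558 and 0.108, and 0.0502 for miR-132-3p. Without normal-pressure library 2 it was 0.0636 for miR-212-5p and 0.0833 for miR-202-3p, which also did not pass without normal-pressure library 1 (0.0779) or with edgeR (0.0505).

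The miR-183, miR-96 and miR-182 cluster, expressed in sensory and epithelial cells and also counted in the granulosa and luteal list, passed as lower (camera adjusted p = 0.00141, median log2 change -1.20). It had an adjusted p = 0.557 with an estimated correlation. Of its 3 tested members, miR-96-5p fell, from 25.2 ± 8.75 to 9.71 ± 2.50 RPM (SD, n = 3), with limma adjusted p = 0.0374; adjusted over the list alone all 3 were lower. miR-182-5p had a log2 change of -1.20 with adjusted p = 0.0810. The precursors lie on chromosome 6, minus strand, at 30169446 to 30169551 for miR-96 and 30165918 to 30165992 for miR-182. miR-96-5p did not pass without normal-pressure library 2 (adjusted p = 0.0833) or 3 (0.0909), or without hypobaric library 1 (0.0718), 2 (0.161) or 3 (0.0582).

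The miR-17 to miR-92 cluster with its paralogs, linked to cell proliferation, passed as higher (camera adjusted p = 0.00479), with a median log2 change of 0.65, or 0.50 above that of all tested miRNAs. It had an adjusted p = 0.657 with an estimated correlation. Of its 15 tested members, 1 rose over all miRNAs tested and 9 rose adjusted over the list alone. miR-19b-3p rose from 137 ± 25.8 to 353 ± 110 RPM (SD, n = 3), limma adjusted p = 0.0247; its precursors lie in an exon of Mir17hg on chromosome 14 (115044305 to 115044391) and on chromosome X (52741983 to 52742066). miR-20a-5p had a log2 change of 0.90 with adjusted p = 0.0837. The list did not pass with a filter at a mean of at least 10 RPM (adjusted p = 0.0630). miR-19b-3p did not pass without normal-pressure library 1 (0.0605) or 2 (0.0833) or hypobaric library 1 (0.111) or 2 (0.107).

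The Dlk1-Dio3 imprinted cluster on chromosome 12 passed as higher (camera adjusted p = 0.0358), with a median log2 change of 0.30, or 0.15 above that of all tested miRNAs. It had an adjusted p = 0.657 with an estimated correlation. Of its 52 tested members, 1 rose over all miRNAs tested and 5 adjusted over the list alone. miR-434-3p rose from 75.5 ± 2.94 to 156 ± 30.0 RPM (SD, n = 3), with limma adjusted p = 0.0213, and miR-410-3p had a log2 change of 0.98 with adjusted p = 0.0555. The precursor of miR-434 (109594506 to 109594599) lies opposite a coding exon of Rtl1. The list did not pass with the replicate number as a block (adjusted p = 0.0730), with DESeq2 (0.132), annotated miRNAs only (0.0592), a mean of at least 10 RPM (0.399) or a GC correction (0.0730), nor without normal-pressure library 1 (0.0543) or 3 (0.0838) or hypobaric library 1 (0.108) or 2 (0.0652). miR-434-3p passed in 13 of 23 alternatives, and not with the block (0.0505), edgeR (0.0819) or any of the 4 other scalings (0.0599 to 0.0833), nor without those same libraries (0.0662, 0.0754, 0.0665 and 0.0696).

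**Figure D3:**
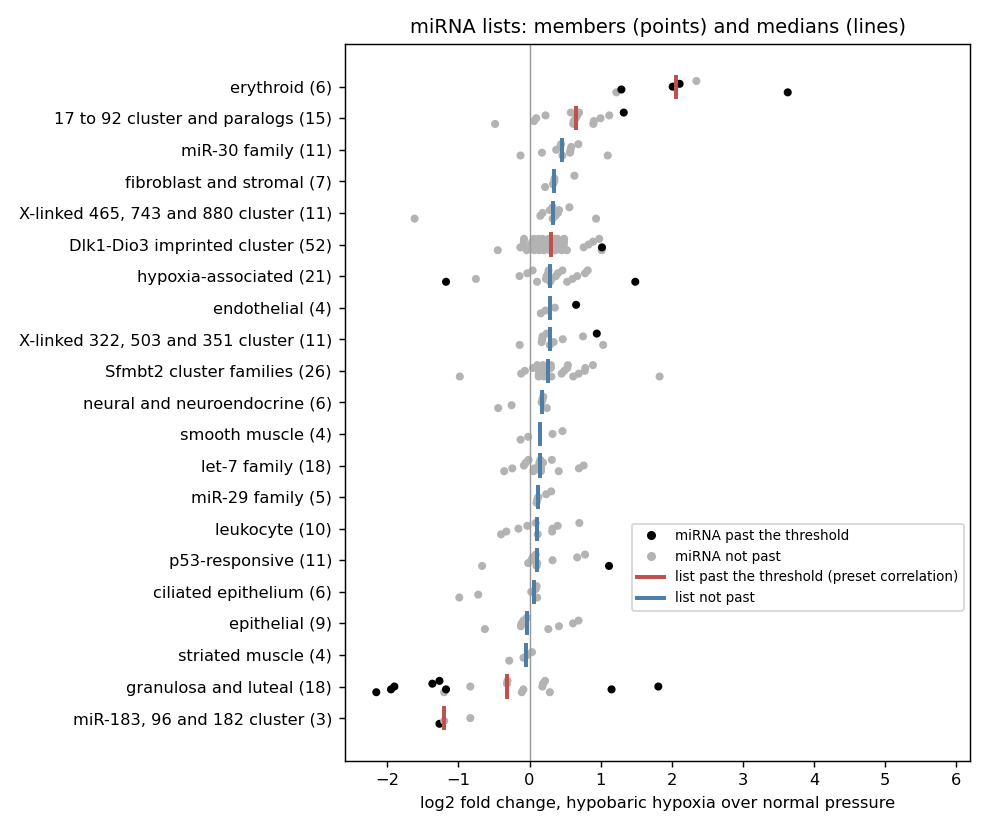
Log2 fold change of the tested members of each of the 21 tested miRNA lists (points, black for miRNAs past the threshold), with the list's median (line, red for the 5 lists that passed with the preset correlation) and its number of tested members in parentheses. miR-199a-3p and miR-199b-3p, at 6.54 and -7.25, belong to the fibroblast list and are not drawn.

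The fibroblast and stromal list held the 2 largest changes among the tested names as deposited, in opposite directions. miR-199a-3p went from 31.0 ± 21.1 to 2632 ± 425 RPM (SD, n = 3) and miR-199b-3p from 2006 ± 424 to 21.6 ± 26.4 RPM (SD, n = 3), with limma adjusted p = 2.27e-05 and 0.00111. The miR-199a precursors lie on chromosome 9 (21496495 to 21496564) and, in an exon of Dnm3os, on chromosome 1 (162217814 to 162217923), and that of miR-199b on chromosome 2 (32318460 to 32318569). They are antisense to introns of the dynamin genes Dnm2, Dnm3 and Dnm1. On the 3p arm the miR-199b precursor shares 28 and 27 consecutive bases with the miR-199a precursors, so reads can be assigned to either name. Summed, both were at 2037 ± 443 RPM at normal pressure and 2654 ± 445 RPM under hypobaric hypoxia (SD, n = 3), a log2 change of 0.39 ± 0.20 (SE) with adjusted p = 0.281. The other arms, miR-199a-5p and miR-199b-5p, both had log2 changes of 0.35, with adjusted p = 0.344 and 0.464. The list had 1 higher, 1 lower and 5 of 7 not past the threshold, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.428, median log2 change 0.35).

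**Figure D4:**
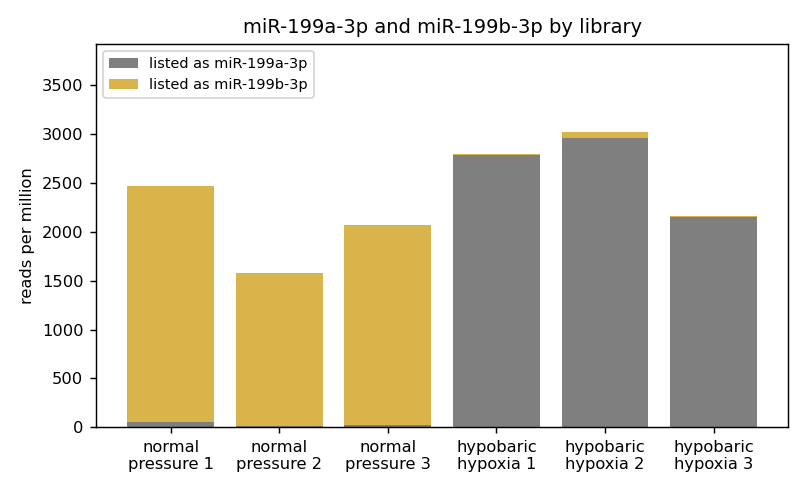
RPM listed as miR-199a-3p (grey) and as miR-199b-3p (yellow) in each of the 6 libraries, stacked from 0. Most reads carry the name miR-199b-3p in the 3 normal-pressure libraries and miR-199a-3p in the 3 hypobaric ones, while the stacked total averages 2037 and 2654.

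In 3 other lists that did not pass, 1 member rose. In the endothelial list (4 tested, median log2 change 0.29, camera adjusted p = 0.266) it was miR-10b-5p, encoded in introns of Hoxd3 and Hoxd4, from 5189 ± 837 to 8113 ± 621 RPM (SD, n = 3), limma adjusted p = 0.0447. It passed in 9 of 23 alternatives and not without normal-pressure library 1 (0.0863) or 2 (0.0558) or hypobaric library 1 (0.103), 2 (0.194) or 3 (0.0966). The call was also lost with all 4 other scalings (adjusted p from 0.0599 to 0.321), the replicate block (0.0505) and edgeR (0.0819). No filter (0.0985), no variance trend (0.103) and the GC correction (0.0561) ended it too. In the p53-responsive list (11 tested, median 0.10, adjusted p = 0.609) it was miR-16-5p, also abundant in blood cells, from 4000 ± 1118 to 8437 ± 588 RPM (SD, n = 3) with limma adjusted p = 0.0161. It did not pass without hypobaric library 1 (0.0797) or 2 (0.0696). In the X-linked miR-322, miR-503 and miR-351 cluster (11 tested, median 0.29, adjusted p = 0.146) it was miR-322-3p, with a log2 change of 0.95 and adjusted p = 0.0352. It passed in 14 of 23 alternatives: all 4 other scalings (0.0527 to 0.0833), edgeR (0.0745) and leaving out normal-pressure library 2 (0.0877) or 3 (0.103) or hypobaric library 1 (0.159) or 2 (0.147) ended that call. Adjusted over the list alone, the counts were the same in the endothelial and p53 lists, and 3 rose in the X-linked list.

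In the other 11 tested lists no member passed in limma; 15 of their 110 tested members had an unadjusted p under 0.05, edgeR called 0 and DESeq2 4. These lists did not pass either. Camera adjusted p was 0.899 for the leukocyte list (10 tested), 0.785 for smooth muscle (4), 0.428 for striated muscle (4), 0.899 for epithelial (9), 0.203 for ciliated (6) and 0.609 for neural miRNAs (6). It was 0.979 for the let-7 (18), 0.978 for the miR-29 (5) and 0.0604 for the miR-30 family (11), 0.428 for the X-linked miR-465, miR-743 and miR-880 cluster (11), and 0.203 for the Sfmbt2 families (26). Median log2 changes ran from -0.06 in striated muscle to 0.46 in the miR-30 family. In the leukocyte, ciliated and neural lists the median was above 0 (0.10, 0.06 and 0.18) while camera pointed down, and in the epithelial list the median was -0.04 and the mean 0.11. miR-150-5p, of lymphocytes, had a log2 change of 0.70 with adjusted p = 0.0827. Adjusted over the list alone 1 member was lower, miR-449a-5p of the ciliated list (limma adjusted p = 0.0324). Its log2 change was -0.99, with limma adjusted p = 0.0810 over all miRNAs tested. miR-465c-3p was at 0, 5.32 and 3.56 RPM in normal-pressure libraries 1, 2 and 3 and at 0 in all 3 hypobaric libraries, where 3 reads would be 0.141 to 0.143 RPM. It shares sequence with miR-465b-3p, and their sum was at 4.13 ± 1.03 and 3.16 ± 2.76 RPM (SD, n = 3), with adjusted p = 0.475. The miR-290 to miR-295 cluster had 0 members above the filter, and of the hepatocyte list 2 were, so neither was tested.

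Outside the lists, 3 further calls were made. miR-335-5p, encoded in an intron of the imprinted gene Mest on chromosome 6 (30741299 to 30741396), rose from 5.69 ± 0.680 to 15.5 ± 3.55 RPM (SD, n = 3), limma adjusted p = 0.0114. miR-15b-5p, named after its values were seen because it is the remaining call, rose by 0.87 ± 0.16 (SE) on the log2 scale, adjusted p = 0.0148. A predicted miRNA (miR389-3p) fell from 35.4 ± 2.44 to 10.5 ± 1.29 RPM (SD, n = 3), adjusted p = 0.00159. Without hypobaric library 1 or 2, miR-335-5p (0.0663 and 0.0696) and miR-15b-5p (0.0787 and 0.0699) did not pass.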

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

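Scaling to miRNA reads, summed names, the GC correction and the run without normal-pressure library 2 and hypobaric library 3 were chosen after seeing the data. All 23 calls kept their direction under each alternative in which they were tested under their own name, and miR-451a, miR-212-3p and miR-132-5p passed in all 23 alternatives. In none of the 23 calls did the groups overlap, so leaving out libraries or changing the pseudocount or filter could not reverse a direction. Other variance fits and the replicate block leave the log2 change as it is. The cause was not tested for the changes below. The sources used here do not say whether the replicate numbers pair the libraries. Correlations of same-numbered deviations were 0.35, -0.47 and -0.29, which with 3 libraries per group cannot decide it. With the replicate block 15 were higher and 8 lower, 21 of the 23 calls were shared, and 4 lists passed. Against 23 calls (15 higher, 8 lower) and 5 lists, DESeq2 called 63 (32 and 31), and without normal-pressure library 2 and hypobaric library 3 there were 49 (36 and 13). Lower calls numbered 14 with median-of-ratios or quantile scaling and with the edgeR count test, which changes test and scaling together, and 19 with totals less the 10 most abundant or with miRNA reads. Lists past the threshold numbered 0 with an estimated correlation (1 had an unadjusted p under 0.05), 1 with fry, 2 at a mean of at least 10 RPM and 9 without a filter. Leaving out 1 library each gave 10 to 34 calls (5 to 25 higher, 4 to 9 lower) and 4 to 7 lists. Depth limits the low miRNAs, since 1 read is worth 0.0443 to 0.0481 RPM.

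Among the calls only miR-199b-3p changed sign, to 0.391 when summed with miR-199a-3p. The other sign changes were in values not past the threshold. With median-of-ratios scaling let-7a-5p was at -0.0179, miR-181a-5p at -0.0449, and the p53, leukocyte and ciliated list medians at -0.0432, -0.0179 and -0.0930. With quantile normalization let-7c-5p was at -0.0355, miR-181a-5p at -0.0510, and the p53, leukocyte, smooth muscle, ciliated and let-7 medians at -0.0815, -0.0531, -0.00401, -0.157 and -0.0485. With totals less the 10 most abundant, let-7c-5p was at -0.0584, miR-99a-5p at -0.0313, miR-126a-3p at -0.0902, let-7a-5p at -0.115, miR-181a-5p at -0.142 and miR-29c-3p at -0.00457. The same 5 medians were then at -0.140, -0.0895, -0.0878, -0.189 and -0.0869, with the neural list at -0.0125 and the miR-29 family at -0.0132. With miRNA reads, let-7c-5p was at -0.0172, miR-126a-3p at -0.0490, let-7a-5p at -0.0739 and miR-181a-5p at -0.101, and the 5 medians at -0.0991, -0.0582, -0.0546, -0.148 and -0.0457. With edgeR, miR-126a-3p was at -0.0294, let-7a-5p at -0.0472, miR-181a-5p at -0.0808, and the 5 medians at -0.0455, -0.0191, -0.0403, -0.113 and -0.0370. With DESeq2 these 8 values were -0.0192, -0.0363, -0.0696, -0.0371, -0.00228, -0.0292, -0.103 and -0.0268. At a mean of at least 10 RPM the neural median was -0.252. With the GC correction miR-143-3p was at 0.0180 and the epithelial median at 0.0413. Without normal-pressure library 2 and hypobaric library 3 the epithelial, ciliated and neural medians were 0.0339, -0.0443 and -0.00756. Leaving out 1 library each gave -0.119 to 0.101 for miR-143-3p, -0.356 to 0.127 for miR-206-3p, and medians of -0.253 to 0.182 for the ciliated, -0.150 to 0.115 for the epithelial, -0.0191 to 0.354 for the neural and -0.0368 to 0.239 for the p53 list.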

Other observations

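All tests of explanations and the summed values here were chosen after the values were seen, except the counts over other splits of the libraries. Those counts cannot decide about chance, since 3 against 3 libraries make 10 splits: 1 of the 10 splits gave as many calls as the real 23, the real one itself, and the highest other had 1. For calls in 1 direction (15 higher, 8 lower) it was again 1 of the 10 splits, with at most 1 call in another, and for the 5 lists 1 of the 10 splits, with at most 4 in another.

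The 5p arms of miR-486a and miR-486b, which did not pass under separate names, summed to 33.6 ± 10.1 RPM at normal pressure and 120 ± 13.8 RPM under hypobaric hypoxia (SD, n = 3), a log2 change of 1.85 ± 0.25 (SE) with limma adjusted p = 0.00063. With the values of shared sequences summed, 30 of 440 miRNAs passed, 21 higher and 9 lower. Among those not past the threshold with the values as deposited were miR-182-5p at -1.20 and miR-449a-5p at -0.99, miR-17-5p at 1.12 and, of the Dlk1-Dio3 cluster, miR-323-3p at 1.02, miR-410-3p at 0.98, miR-496a-3p at 0.89 and miR-412-5p at 0.76. None of these shares a sequence with another miRNA, and their log2 changes equalled those of the values as deposited. Only the fit and the adjustment differed: miR-182-5p had SE 0.329 and limma adjusted p = 0.0810 as deposited, and 0.308 and 0.0337 here. Their passing therefore comes from the fit and adjustment over the summed set, not from reads added to these miRNAs.

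The opposite changes of miR-199a-3p and miR-199b-3p are a candidate for a naming effect. A read within the 28 or 27 bases that the precursors share on the 3p arm cannot tell the names apart. For such reads only the sum can be read as a level. Their sum changed by 0.39 ± 0.20 (SE), against 6.54 and -7.25 for the separate names. A shift of expression from the miR-199b locus to the miR-199a loci would lower miR-199b-5p, cut from the same precursor, but that arm was at 0.35 ± 0.26 (SE). Reads of a sequence shared by both precursors, assigned mostly to 1 name per library, may therefore account for both calls. Why the assigned name follows the groups was not tested.

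The rise of the erythroid miRNAs was not removed by scaling: the lowest median log2 change of the list over the alternative scalings was 1.91. Those scalings moved the median of all tested miRNAs only from 0.15 to between -0.05 and 0.03. They could therefore not have removed a change of this size. More RNA of red blood cells in the hypobaric libraries is a candidate explanation, since the erythroid members rose together, the smallest change being 1.73 once the values of shared sequences were summed. These members come only from the locus of miR-451a and miR-144 and that of miR-486, so they are not independent of each other. Whole blood with its white cells cannot be told apart from red cells alone: the leukocyte list's median was 0.10, but the ovary expresses its members at normal pressure, which could hide a small share. Whether the animals had more red cells or more blood stayed in the tissue at collection was not tested. The 6 tested members stand in no other list, and the most abundant, miR-451a, took 3.04% of miRNA reads under hypobaric hypoxia and 0.296% at normal pressure.

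The fall of miR-132, miR-212, miR-21a and miR-96 (6 miRNAs with both arms of miR-132 and miR-212) was not removed by scaling either: their highest median over the alternative scalings was -1.75. As above, those scalings shifted the tested miRNAs too little to have removed a fall of this size. After the GC correction, which used the GC content of the precursor arms, all 6 were still past the threshold. It moved miR-212-5p from -1.95 to -1.74 and miR-132-5p from -1.90 to -1.85. In the other direction, it moved miR-21a-5p from -1.17 to -1.23. Shifts this small could not have removed the fall, so this test cannot decide about GC content. The GC content of the mature miRNAs was not tested. Dilution by red-cell RNA would lower other miRNAs alike, but the median of the remaining tested miRNAs was 0.15. That median shifts with the scaling, and the test could hardly have come out otherwise. The larger share of miR-451a alone would change the other miRNAs by only -0.04 on the log2 scale. A dilution of that size is far smaller than the fall of these 6. Members of the granulosa and luteal list did not all move the same way: 12 of the 18 tested had negative log2 changes and 6 positive ones. Of the positive ones, only miR-202-3p (1.81) and miR-202-5p (1.15), both arms of the same precursor, passed the threshold. An effect of the exposure on granulosa or luteal cells stays untested, as does any difference in cycle stage, chamber housing or the dose of the synchronizing hormones, which the labels state for the hypobaric group alone.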
